A study of Mus musculus with 18 samples.

How the data were processed

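Total RNA from 18 mouse embryonic stem cell samples was hybridised to whole-transcript expression arrays by the submitters, 12 from R1E cells and 6 from p53-/- cells. The deposited values are log2 intensities, 1 per probe set and array. Per the submitters' processing notes, the R1E arrays were processed with Affymetrix Expression Console 1.1 and the p53-/- arrays with RMA in Partek 6.4. The algorithm run in Expression Console is not given in the sources used here. Because the sets were normalized separately, gene levels were tested only within a set, and across sets the difference of the adriamycin effects was tested. Starting levels of gene groups were set side by side across the sets after the array medians were aligned, and again after the p53-/- values were multiplied by 1.155, the ratio of the SD of gene levels in R1E mock to that in untreated p53-/- arrays. Such gaps rest on the alignment and had no test of their own. Genotype, cell line, set and processing tool cannot be told apart in that difference.

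The deposited table held 28853 probes, of which 28815 had values on all 18 arrays. The probe annotation gave 1 gene symbol for 21780 of these, several for 1605 and none for 5430, and only probes with 1 symbol were named. Of those, 21689 had an Entrez ID found in the RefSeq table of assembly GRCm38.p6, used for current symbols and for gene span, and 0 symbols changed. For the 998 genes with more than 1 probe the probe with the highest mean over the 18 arrays was used, leaving 19935 genes, 99.6% of them with a span. The array's genome build is not given in the sources used here, so no coordinates are printed. Trp53, Cdkn1a and Bax, planned for a fixed panel, had no probe naming that gene alone in the tables used, and were not analysed here. The planned check of the p53-/- label on Trp53 was therefore not made.

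Groups were taken from the labels. Comparisons were fitted in limma 3.58.1 (R 4.3.3) on the deposited log2 values with lmFit and eBayes, with no further normalization and no filter on dim probes. The R1E comparisons used 1 fit over 12 arrays, the p53-/- comparison its 6 arrays, and the difference of effects 1 fit over 18 arrays. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Errors of changes are moderated standard errors. Gene lists, 39 in all, were tested with camera at a preset correlation of 0.01, adjusted over the 39 lists per comparison. Camera with an estimated correlation and fry, which tests whether a list's own genes move one way on balance, were run beside it. Of the list calls 4 held with an estimated correlation for adriamycin in R1E, 3 for UV and 2 for the difference of effects, and none did for adriamycin against UV, where 7 lists had an unadjusted p below the threshold and fry called 26 of the 39 lists. Genes above 100 kb in span were tested with camera as 1 set.

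The gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and falls among called genes whose groups did not overlap, a fixed panel, and up to 4 members of each called list in its direction and 2 against it. Clone and prediction names, olfactory, vomeronasal, histone and small RNA genes were left out of the largest changes. For the difference of effects no condition on overlap applied. Levels of Prdm14 and Nr0b1 in untreated p53-/- cells, given as deposited, were picked after their values were seen.

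Scripts were tested on simulated arrays drawn from the real gene means and spreads, with 200 of 19935 genes changed, 5 simulations per comparison. For adriamycin in R1E 98.6% of 1.5-fold and 100% of 2-fold changes were recovered, with 4.7% of calls false. For UV these were 96.4%, 99.8% and 4.0%, and for adriamycin against UV 97.0%, 100% and 5.1%. For p53-/- cells they were 19.4%, 69.4% and 4.3%, and with 4000 changed genes 75.8%, 95.9% and 4.4%. For the difference of effects they were 61.8%, 94.0% and 38.4%: the shared spread understates the error of the noisier p53-/- set. That fit was kept as fixed beforehand, and a fit with each set's own spread was added and is printed beside it.

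Alternatives covered normalization, centring, a dim-probe filter, the choice of probe, the eBayes prior, the arrays in the fit, a replicate block, a fold threshold and each array left out. Quantile normalization for the list tests, camera with array weights and the difference with each set's own spread were chosen after seeing the data.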

Results

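Messenger RNA levels were measured on 18 whole-transcript arrays from mouse embryonic stem cells exposed to DNA-damaging treatments. Of these, 12 arrays came from R1E cells, a mouse embryonic stem cell line grown with leukemia inhibitory factor, and 6 came from p53-/- cells. R1E cells were mock treated, given adriamycin (doxorubicin, a topoisomerase II poison that breaks DNA) at 0.5 µM for 8 hours, or exposed to ultraviolet light (UV) at 25 J/m² and examined at 8 hours, with n = 4 arrays per group. The p53-/- cells were untreated or given 0.5 µM adriamycin for 8 hours, with n = 3 arrays per group. Array medians lay between 5.30 and 5.61 on the log2 intensity scale, and the number of arrays limits the precision of every value. The labels do not say whether arrays of a group came from separate cultures, so p-values measure the spread between arrays, which may be technical. The p53-/- arrays spread more than the R1E arrays, with a median standard error (SE) of a change of 0.140 against 0.063. The level of Trp53, the gene named by the p53-/- label, was not analysed here, so the label rests on the submitters' description alone.

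The first comparison asked what adriamycin changed in R1E cells. Most known p53 targets rose and most genes of the pluripotency network fell. The largest rise was in Them5, an acyl-CoA thioesterase, at 24.4-fold (log2 change 4.61 ± 0.06 SE), followed by Alox5, the 5-lipoxygenase that starts leukotriene synthesis, at 15.7-fold (3.98 ± 0.05). Ppp1r36 (13.1-fold), Tap1, a subunit of the peptide transporter of antigen presentation (11.6-fold), Scn3b (11.4-fold), Gpx6 (11.2-fold), Cpz (log2 change 3.46) and the death receptor Fas (9.07-fold) came next. The largest falls were in the transcription factors Zic2 (8.00-fold), Prdm14 (6.81-fold), Zic5 (6.53-fold), Otx2 (5.38-fold) and Nr0b1 (4.99-fold), with Emp1 (6.19-fold), the growth factor Fgf17 (5.98-fold) and the peptide hormone Apela (5.70-fold). A second, dimmer probe of Zic5 gave a log2 change of -0.78 against -2.71 for the probe used. By the rule for named genes, every treated array of these 16 genes lay outside the range of the mock arrays. That was a condition of the choice and no evidence for these genes. Of all genes 45.6% met it, where chance gives 2.9% with 4 arrays against 4.

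Of 46 measured p53-activated targets, 42 rose and 2 fell, and the counts were 42 and 2 when adjusted over the list alone. Mdm2, the ubiquitin ligase that degrades p53, rose 3.71-fold (log2 change 1.89 ± 0.05 SE, adjusted p = 3.25e-14), Ccng1 rose 1.84-fold, Plk2 7.77-fold and Dcxr 5.76-fold. The exceptions were Plk3, with a log2 change of -0.51, and Tigar, at -0.31. The list stood above other genes (limma camera, adjusted p = 7.95e-23), also with an estimated correlation (adjusted p = 0.00692). Of 44 members of the core pluripotency network, 41 fell and 1 rose, or 42 and 1 adjusted over the list alone (adjusted p = 3.24e-18, and adjusted p = 0.00692 with an estimated correlation). Nanog had a log2 change of -1.12 ± 0.07, Zfp42 of -1.75 ± 0.06, Mycn of -1.83 ± 0.05, Esrrb of -0.72 ± 0.04, Sox2 of -0.55 ± 0.07 and Klf4 of -0.44 ± 0.06. Pou5f1, which encodes OCT4, moved least of these, at -0.18 ± 0.05 (adjusted p = 0.00917). Lefty1, a Nodal antagonist, rose 1.78-fold.

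Lists of FGF and ERK signalling, polycomb, DNA methylation and LIF response genes were called downward after adriamycin in R1E. In the FGF and ERK signalling list 20 of 23 genes fell and 2 rose, the same numbers adjusted over the list alone, with Etv1 at -2.08, Fgf15 at -1.97 and the feedback inhibitor Spry4 at -1.96 on the log2 scale. The receptor gene Fgfr4 went the other way, rising 4.53-fold. A second probe of Etv1 gave -1.82. Among polycomb and trithorax components 22 of 28 fell and 1 rose (23 and 1 adjusted over the list alone), led by Phf19 at -1.21, Kmt2c at -1.04 and Jarid2 at -0.83. Both lists were called, with adjusted p = 1.18e-06 and 9.17e-07, and each had adjusted p = 0.00692 with an estimated correlation. Among DNA methylation and chromatin silencing genes 21 of 25 fell and 3 rose, the same adjusted over the list alone, including Tet2 at -1.55, Dnmt3l at -1.03 and Dnmt3a at -0.88 (adjusted p = 4.28e-06, and adjusted p = 0.0957 with an estimated correlation). In the LIF, STAT3 and BMP response 15 of 23 fell and 4 rose, or 16 and 4 adjusted over the list alone. Bcl3 was at -1.59 and Pim1 at -1.39, while Id2 rose 2.76-fold (adjusted p = 0.000811, and adjusted p = 0.181 with an estimated correlation).

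Lists of histone, mitosis and replication genes were also called downward. All 24 measured replication-dependent histone genes fell after adriamycin, also adjusted over the list alone, with H2ac4 at -1.85 ± 0.14, H2bc3 at -1.45 ± 0.08 and H2bc4 at -1.36 ± 0.14 (adjusted p = 2.09e-08, and adjusted p = 0.0673 with an estimated correlation). Histone genes have near-identical copies, so a single histone probe can read several of them. Of 40 G2/M and mitosis genes 32 fell and 5 rose, or 34 and 5 adjusted over the list alone, with the mitotic kinase Plk1 at -1.23 and Kif23 at -0.90, while Fam83d rose 2.34-fold (adjusted p = 1.76e-07, and adjusted p = 0.0673 with an estimated correlation). Of 41 replication and G1/S genes 21 fell and 3 rose, or 23 and 3 adjusted over the list alone, with Ccne1, encoding cyclin E1, at -0.89 (adjusted p = 0.00625, and adjusted p = 0.296 with an estimated correlation). The replication call also ended with quantile normalization (adjusted p = 0.223).

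Of the other lists called after adriamycin in R1E, 4 were downward and Wnt ligands upward. Cholesterol synthesis had 17 of 20 genes lower and none higher, the same adjusted over the list alone, with Ebp at -1.05 and Sqle at -0.74 (adjusted p = 5.11e-05, and adjusted p = 0.353 with an estimated correlation). Glycolysis and hypoxia response genes had 20 of 27 lower and 2 higher, or 21 and 3 adjusted over the list alone, with Ndrg1 at -1.58 and Kdm3a at -1.47, while Pfkm rose 1.95-fold (adjusted p = 4.63e-05, and adjusted p = 0.229 with an estimated correlation). Ribosome biogenesis genes had 26 of 41 lower and 4 higher, or 27 and 5 adjusted over the list alone, with Rrs1 at -0.88 (adjusted p = 0.00062, and adjusted p = 0.229 with an estimated correlation). The unfolded protein and integrated stress response list had 20 of 31 lower and 6 higher, or 21 and 6 adjusted over the list alone, with Atf4 at -1.35 and Chac1 at -1.31, while the p53 target Sesn2 rose 1.87-fold (adjusted p = 0.00508, and adjusted p = 0.147 with an estimated correlation). Wnt ligands rose, 11 of 19 with none lower, the same adjusted over the list alone. Wnt8b rose 4.22-fold, Wnt3 3.92-fold, Wnt4 2.32-fold (log2 change 1.22, against 0.57 for its other probe) and Wnt9a 2.05-fold (adjusted p = 0.00281, and adjusted p = 0.454 with an estimated correlation). The Wnt list follows an earlier report on these cells and is not independent evidence of its direction.

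In all, 4397 of 19935 genes were higher and 5110 lower after adriamycin in R1E (limma, Benjamini-Hochberg), of which 779 and 292 changed at least 2-fold. The balance of small changes depended on centring: with each array centred on its median, all changes shifted by -0.125 on the log2 scale, giving 3281 higher and 9640 lower, so 25.4% of calls were higher in place of 46.3%.

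**Figure D1:**
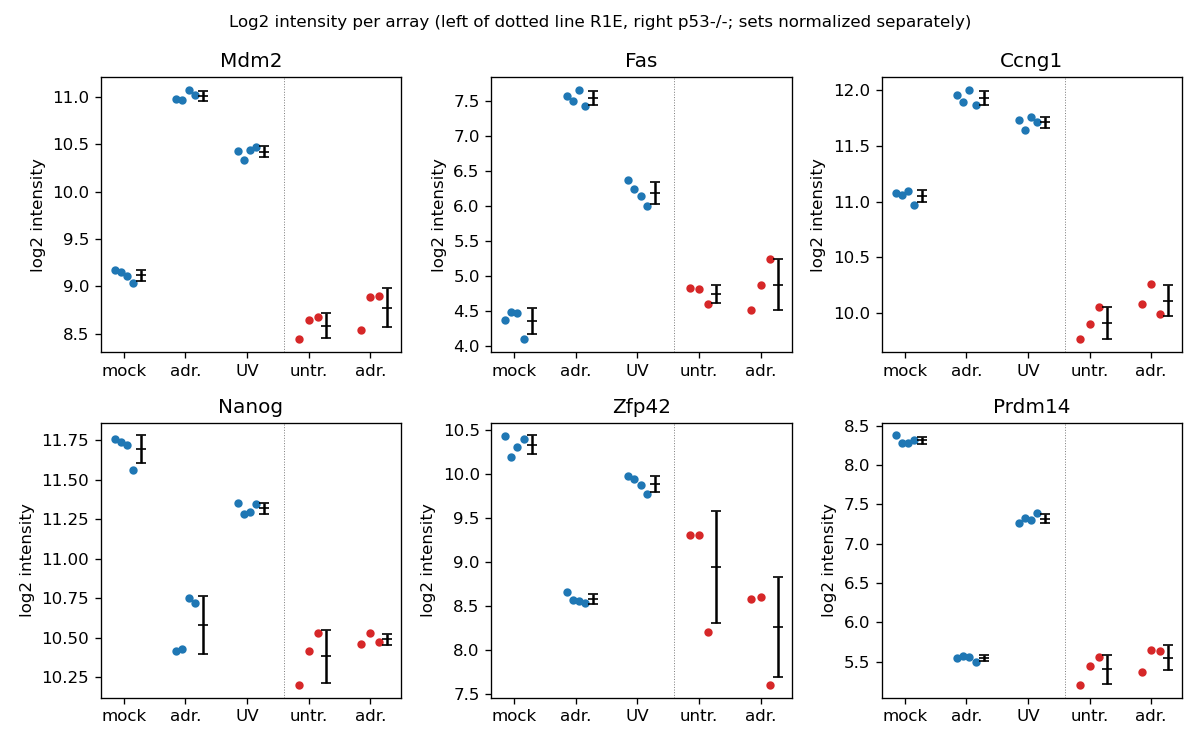
Log2 intensity (vertical axes) of 6 genes on each array, by group (horizontal axes), with points for arrays and bars for the mean ± SD (n = 4 in R1E, n = 3 in p53-/-). Mdm2 averaged 9.12 in R1E mock, 11.01 after adriamycin and 10.42 after UV, and 8.59 and 8.78 in untreated and treated p53-/- cells, a set normalized separately.

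The next comparison asked what UV changed in R1E cells. Most known p53 targets rose again and most pluripotency genes fell, by less than after adriamycin for Nanog and Zfp42. Them5 rose 9.83-fold (log2 change 3.30 ± 0.06 SE), Tap1 8.08-fold, Gpx6 8.04-fold, the kinase gene Plk2 6.39-fold, Scn3b 6.08-fold, Zfp750 5.82-fold and Insyn2a 5.80-fold, and Ppp1r36 had a log2 change of 2.70. The largest falls were Lef1, a Wnt-pathway transcription factor (3.49-fold, log2 change -1.80 ± 0.07), Etv1 (3.40-fold), Gtdc1 (3.35-fold), Cask (3.23-fold), Gphn, which encodes the synaptic scaffold gephyrin (3.08-fold), Sfmbt2 (3.00-fold), Lpp (2.99-fold) and Arhgap42 (2.91-fold). The other probes of Lpp gave -0.71 and -0.24 against -1.58 for the probe used, and the other probe of Arhgap42 gave -0.71 against -1.54. For Etv1 the other probe gave -1.37 against -1.77. Mdm2 rose 2.47-fold, Fas 3.56-fold and Ccng1 1.58-fold.

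Of the 46 p53-activated targets 40 rose and 1 fell after UV, or 40 and 2 adjusted over the list alone, Btg2 rising 5.34-fold and Dcxr 4.35-fold (adjusted p = 4.83e-20, and adjusted p = 0.0186 with an estimated correlation). In the pluripotency network 33 of 44 fell and 2 rose, or 34 and 2 adjusted over the list alone (adjusted p = 1.18e-10, and adjusted p = 0.0322 with an estimated correlation). Otx2 was at -1.12, Jarid2 at -0.80, Sox2 at -0.50, Zfp42 at -0.44 and Nanog at -0.37 on the log2 scale. Pou5f1, at -0.07, and Klf4, at -0.14, did not pass the test. Polycomb and trithorax components had 20 of 28 lower and 1 higher, or 21 and 1 adjusted over the list alone, with Kmt2c at -1.34 and Kdm6a at -1.05 (adjusted p = 3e-06, and adjusted p = 0.0186 with an estimated correlation).

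Immediate early and AP-1 genes were called upward after UV, 18 of 35 higher and 5 lower, or 19 and 5 adjusted over the list alone. Fosl1 rose 3.83-fold, Jun 2.51-fold and Atf3 2.31-fold, while Ier3 was at -0.85 (adjusted p = 0.000956, and adjusted p = 0.153 with an estimated correlation). Notch signalling had 12 of 24 higher and 6 lower, the same adjusted over the list alone, Nrarp rising 4.45-fold, Jag2 2.79-fold and Dll1 2.56-fold (adjusted p = 0.028, and adjusted p = 0.306 with an estimated correlation). Wnt ligands had 12 of 19 higher and none lower, or 13 adjusted over the list alone, Wnt8b rising 2.67-fold and Wnt3 2.51-fold (adjusted p = 0.00113, and adjusted p = 0.35 with an estimated correlation). Wnt nuclear factors, feedback genes and inhibitors had 11 of 25 lower and 3 higher, or 12 and 4 adjusted over the list alone, with Sfrp1 at -0.77 (adjusted p = 0.045, and adjusted p = 0.306 with an estimated correlation). Homologous recombination and Fanconi anaemia genes had 18 of 31 lower and 7 higher, or 18 and 8 adjusted over the list alone, with Fancl and Rad51b both at -0.88 (adjusted p = 0.0184, and adjusted p = 0.447 with an estimated correlation). With dim genes left out the UV calls ended for Notch signalling (adjusted p = 0.0606), for Wnt nuclear factors and for homologous recombination (both adjusted p = 0.0898). The recombination call also ended with quantile normalization (adjusted p = 0.0948). That of the Wnt nuclear factors ended with each array centred on its median (adjusted p = 0.0859) and without any 1 of mock replicates 1, 3 and 4 or UV replicates 1 and 3 (adjusted p from 0.0509 to 0.057).

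The remaining lists called after UV all moved down. DNA methylation and chromatin silencing genes had 20 of 25 lower and none higher, the same adjusted over the list alone, with Atrx at -0.72 (adjusted p = 3.21e-07, and adjusted p = 0.0734 with an estimated correlation). Glycolysis and hypoxia response genes had 21 of 27 lower and 2 higher, the same adjusted over the list alone, with Ndrg1 at -0.97 (adjusted p = 1.24e-06, and adjusted p = 0.17 with an estimated correlation). FGF and ERK signalling had 14 of 23 lower and 2 higher, or 14 and 3 adjusted over the list alone, with Fgf17 at -1.06 (adjusted p = 0.00118, and adjusted p = 0.0618 with an estimated correlation). Histone genes had 11 of 24 lower, or 12 adjusted over the list alone, with H2ac4 at -0.81 (adjusted p = 0.00166, and adjusted p = 0.306 with an estimated correlation). G2/M genes had 21 of 40 lower and 7 higher, the same adjusted over the list alone, with Kif14 at -0.56, against 0.05 for its dim other probe (adjusted p = 0.012, and adjusted p = 0.35 with an estimated correlation). The unfolded protein and integrated stress response had 17 of 31 lower and 5 higher, or 17 and 6 adjusted over the list alone, with Atf6 at -0.87 (adjusted p = 0.0311, and adjusted p = 0.306 with an estimated correlation). The calls of these last lists, G2/M genes and the stress response, ended with dim genes left out (adjusted p = 0.0856 and 0.142) and with quantile normalization (adjusted p = 0.235 and 0.216).

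In all, 4515 genes were higher and 4236 lower after UV, 372 and 138 of them by at least 2-fold. With each array centred on its median 35.3% of the calls were higher in place of 51.6%.

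Gene span, the distance from the first to the last annotated base in the GRCm38.p6 RefSeq table, went with lower levels after UV. After UV the 2294 genes above 100 kb had a median log2 change of -0.136, with 1105 lower (48.2%) and 201 higher (8.8%). The 6996 genes under 10 kb had a median of 0.069, with 461 lower (6.6%) and 1717 higher (24.5%). With dim genes left out the median above 100 kb was -0.393 after UV. Genes above 100 kb stood below other genes after UV (camera p = 3.09e-17, and p = 0.000326 with an estimated correlation). Across genes, which are not independent replicates, span and change had a Spearman rho of -0.294 after UV, of -0.141 after adriamycin in p53-/- cells and of 0.035 after adriamycin in R1E, where genes above 100 kb had a median of -0.005 (camera p = 0.35). For adriamycin against UV the rho was 0.403, and for the difference of effects between the lines 0.111. In p53-/- cells the long genes were called downward against other genes (camera p = 0.000337, and p = 0.0703 with an estimated correlation) although their own median was 0.003. Among genes above 100 kb, adriamycin levels exceeded UV levels in R1E by a median of 0.222 (limma camera, adjusted p = 8.5e-28, and p = 4.21e-05 with an estimated correlation), or 0.398 with dim genes left out. The length test comprised 5 comparisons, and the limma camera adjusted p was 7.72e-17 for UV, 0.35 for adriamycin in R1E, 0.000562 for p53-/- cells and 0.0164 for the difference of effects between the lines, whose median was 0 (p = 0.126 with an estimated correlation).

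**Figure D2:**
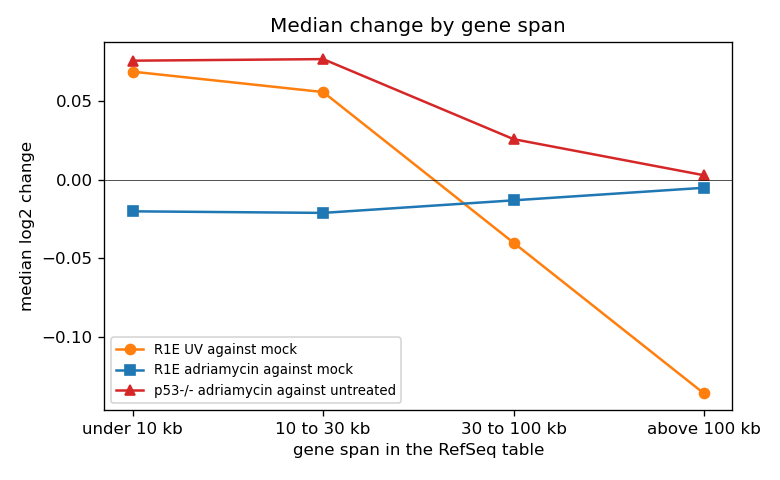
Median log2 change (vertical axis) of genes in 4 classes of RefSeq span (horizontal axis) for 3 comparisons, 1 line each. The UV line falls from 0.069 under 10 kb to -0.136 above 100 kb, while the R1E adriamycin line stays between -0.021 and -0.005 and the p53-/- line falls from 0.076 to 0.003.

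The changes after adriamycin and UV in R1E overlapped. Both treatments raised 2881 genes and lowered 2997, while 576 moved in opposite directions. Independent lists of these sizes would share 995.9 and 1085.8, values that leave out the shared mock arrays. With the mock arrays split 2 and 2 between the treatments, both raised 2329 to 2366 genes and lowered 2379 to 2438. The changes correlated across genes at r = 0.766, against 0.501 in simulated arrays with no effect, a value that comes from the shared mock arrays. The covariance was 0.1345 against a simulated 0.002701, a difference of 0.1318. With the same splits, r lay between 0.712 and 0.763.

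Adriamycin and UV were also compared directly in R1E. Levels were higher after adriamycin for Ano3 (6.55-fold, log2 difference 2.71 ± 0.10 SE), Plxdc2 (5.88-fold), the receptor gene Egfr (4.47-fold), Arhgap20 (3.65-fold), Pakap (3.63-fold), Cyp4f39 (3.54-fold), Alox5 (3.36-fold) and Itga8 (3.36-fold). Levels were lower after adriamycin for Nr0b1 (4.32-fold), Spry4 (4.08-fold), Prdm14 (3.41-fold), Apela (3.41-fold), Zic5 (3.37-fold), Zic2 (3.31-fold), Bmp4 (3.14-fold) and Trh, the thyrotropin-releasing hormone gene (3.14-fold). Fas differed by 2.55-fold, Ccng1 by 1.16-fold and Mdm2 by 0.59 on the log2 scale, each higher after adriamycin. The other probe of Zic5 gave -0.42 against -1.75 for the probe used. Nanog was at -0.74 and Zfp42 at -1.31, while Sox2, at -0.04, and Pou5f1, at -0.11, did not pass the test.

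In the pluripotency network 30 of 44 genes were lower after adriamycin than after UV and none higher, or 31 adjusted over the list alone (adjusted p = 7.47e-12, and adjusted p = 0.0633 with an estimated correlation). Of 46 p53 targets 29 were higher after adriamycin and 3 lower, or 29 and 5 adjusted over the list alone, Apaf1 by 2.38-fold and Polk by 1.85-fold (adjusted p = 8.96e-07, and adjusted p = 0.164 with an estimated correlation). Histone genes were lower in 21 of 24, the same adjusted over the list alone (adjusted p = 1.09e-06, and adjusted p = 0.164 with an estimated correlation). Immediate early genes were lower in 22 of 35 and higher in 1, or 24 and 2 adjusted over the list alone, with Dusp4 at -1.03 and Myc at -0.97 (adjusted p = 3.45e-06, and adjusted p = 0.104 with an estimated correlation). Ribosome biogenesis genes were lower in 30 of 41 and higher in 3, the same adjusted over the list alone, with Nolc1 at -0.72 (adjusted p = 1.19e-05, and adjusted p = 0.164 with an estimated correlation).

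Of the other lists called between the agents, 1 was higher after adriamycin. Homologous recombination and Fanconi anaemia genes were higher in 12 of 31 and lower in 3, or 13 and 3 adjusted over the list alone, with Fancl at 0.67 (adjusted p = 0.0248, and adjusted p = 0.617 with an estimated correlation). The call ended with dim genes left out (adjusted p = 0.142), with quantile normalization (adjusted p = 0.0793) and without adriamycin replicate 3 (adjusted p = 0.0549). The list median of 0.047 became -0.001 with each array centred on its median. G2/M genes were lower in 24 of 40 and higher in 2, or 24 and 3 adjusted over the list alone, with Nek2 at -0.72 (adjusted p = 6.75e-05, and adjusted p = 0.186 with an estimated correlation). Cholesterol synthesis genes were lower in 15 of 20, the same adjusted over the list alone, with Mvd at -0.66 (adjusted p = 6.75e-05, and adjusted p = 0.418 with an estimated correlation). FGF and ERK signalling was lower in 12 of 23 and higher in 4, the same adjusted over the list alone, with Fgf17 at -1.52 (adjusted p = 0.00554, and adjusted p = 0.156 with an estimated correlation). The LIF, STAT3 and BMP response was lower in 12 of 23 and higher in 5, the same adjusted over the list alone, with Spry2 at -1.19 (adjusted p = 0.0333, and adjusted p = 0.418 with an estimated correlation). This call ended with each array centred on its median (adjusted p = 0.0763) and without UV replicate 2 (adjusted p = 0.0543). Ectoderm and neural markers were lower in 14 of 25 and higher in 2, the same adjusted over the list alone, with Nes at -0.57 (adjusted p = 0.0159, and adjusted p = 0.418 with an estimated correlation).

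In all, 3950 genes were higher and 4420 lower after adriamycin than after UV, 213 and 56 of them at least 2-fold, and 11 of 39 lists were called. With each array centred on its median 34.7% of the calls were higher in place of 47.2%.

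The fourth comparison asked what adriamycin changed in p53-/- cells. Of the 19 genes that passed the test 10 were replication-dependent histone genes, all lower, while the other 14 measured histone genes did not pass. H2ac1 fell 3.34-fold (log2 change -1.74 ± 0.17 SE, adjusted p = 0.005), H2ac4 3.17-fold, H2bc14 2.37-fold and H2bc3 2.32-fold. The other falls named by the rule were Nrf1, a regulator of mitochondrial gene expression, at -1.12 ± 0.16, the cadherin gene Cdh11 at -0.98 ± 0.15 and Leng8 at -0.77 ± 0.12. The 3 rises were Procr, the protein C receptor gene (2.01-fold), Muc1 (1.77-fold) and Ldoc1 (1.73-fold). None of these calls held without each array in turn. The limma call of H2ac1 ended without adriamycin replicate 1 or 2 (adjusted p = 0.0785 and 0.0836), and those of H2ac4, H2bc14 and H2bc3 without any 1 of the 3 treated arrays (adjusted p from 0.0785 to 0.113). The calls of Procr, Muc1, Ldoc1, Nrf1, Cdh11 and Leng8 ended without any 1 of the treated arrays or untreated replicate 2, and all of these but Procr without untreated replicate 1 (adjusted p from 0.0836 to 0.326). Quantile normalization ended the calls of Muc1 (adjusted p = 0.0768) and Ldoc1 (adjusted p = 0.0593), as did centring (adjusted p = 0.0707 and 0.0537). Testing all probes ended those of Muc1 (adjusted p = 0.0666), Cdh11 and Leng8 (both adjusted p = 0.0581), and an intensity trend in the prior those of Muc1 and Leng8 (adjusted p = 0.0642 and 0.0758). Mdm2, at 0.19 ± 0.14, Ccng1, at 0.21 ± 0.13, Fas, at 0.13 ± 0.17, Nanog, at 0.11 ± 0.13, and Zfp42, at -0.68 ± 0.31, did not pass the test.

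Of 24 histone genes 10 fell in p53-/- cells, or 17 adjusted over the list alone, with a list median of -0.65 (adjusted p = 7.03e-36, and adjusted p = 0.45 with an estimated correlation). For G2/M and mitosis genes 0 of 40 passed over all genes by limma, 20 had an unadjusted p below the threshold, and 15 were lower adjusted over the list alone, with a list median of -0.31 (adjusted p = 3.95e-20, and adjusted p = 0.45 with an estimated correlation). Of the p53-activated targets 0 of 46 passed and 13 did so unadjusted, 12 of them upward, with a median of 0.169 (camera adjusted p = 0.087). In the pluripotency network 0 of 44 passed and 7 did so unadjusted, each downward, and the list was called downward with a median of -0.007 (adjusted p = 0.00334, and adjusted p = 0.45 with an estimated correlation). That median turned to 0.024 without untreated replicate 2 and to 0.004 without adriamycin replicate 3. Markers of feeder fibroblasts, another cell type such cultures can hold, had a median of -0.163 in p53-/- cells (adjusted p = 7.66e-06, and adjusted p = 0.45 with an estimated correlation) and of -0.033 in R1E cells (adjusted p = 0.856). In all 11 lists were called in p53-/- cells, each downward, and 0 were with an estimated correlation, where 3 had an unadjusted p below the threshold. Fry, a self-contained test, called none of the 11, with adjusted p = 0.0704 for histone genes, and called 1 other list, NF-kB and inflammatory genes, upward (adjusted p = 0.0457). With quantile normalization the camera calls ended for the pluripotency network (adjusted p = 0.1), DNA methylation (adjusted p = 0.153), TGF-beta signalling (adjusted p = 0.15) and transcription elongation (adjusted p = 0.245). The last 3 also ended without untreated replicate 2 (adjusted p from 0.0736 to 0.175), where the TGF-beta median turned from -0.083 to 0.019, and without adriamycin replicate 3 (adjusted p from 0.0571 to 0.0969). TGF-beta signalling and transcription elongation ended with dim genes left out (adjusted p = 0.0817 and 0.0757), the former also without untreated replicate 1 (adjusted p = 0.053) and the latter without adriamycin replicate 1 (adjusted p = 0.112).

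In all 3 genes were higher and 16 lower in p53-/- cells, and 2319 had an unadjusted p below the threshold. With each array centred on its median 4.2% of the calls were higher in place of 15.8%. Untreated replicate 3 stood apart from its group, with a mean correlation to it of 0.987 against 0.9906 and 0.9921 for the others. Without it 135 genes were higher and 307 lower, while without any other single array 0 to 6 genes were called. In simulated arrays with this spread 69.4% of 2-fold and 19.4% of 1.5-fold changes were recovered with 200 changed genes, and 95.9% and 75.8% with 4000.

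The last comparison asked whether the adriamycin effect differed between the lines, through the difference of the effects within each set. The lines also differ in set and processing tool, so the difference cannot be assigned to p53 alone. The effect differed between the lines for most p53 targets and most pluripotency genes. The effect was larger in R1E for Them5 (20.7-fold, log2 difference 4.37 ± 0.14 SE), Cpz (11.5-fold), Ppp1r36 (11.4-fold), Alox5 (11.3-fold), Gpx6 (11.1-fold), Scn3b (9.28-fold), Tap1 (8.82-fold), Pm20d1 (8.32-fold), Fas (8.27-fold) and Mdm2 (3.25-fold). The difference was downward for Prdm14 (-2.92 ± 0.12), Fgf17 (-2.78 ± 0.13), Bmp4 (-2.76 ± 0.16), Zic2 (-2.64 ± 0.15), Zic5 (-2.46 ± 0.11), Apela (-2.44 ± 0.22), Otx2 (-2.41 ± 0.18), Emp1 (-2.37 ± 0.17) and Nanog (-1.22 ± 0.13). The other probe of Zic5 gave a difference of -0.65. For Pou5f1, at -0.23 ± 0.10, and Klf4, at -0.19 ± 0.16, the difference did not pass the test. The errors given here come from the planned fit with 1 spread shared by both sets. That spread understates the error of the p53-/- set. With each set's own spread the SE was 0.166 for Them5, 0.149 for Prdm14, 0.236 for Apela, 0.15 for Nanog and 0.134 for Pou5f1. Untreated p53-/- cells had Prdm14 at 5.41 and Nr0b1 at 8.89, about the levels of treated R1E cells (5.54 and 8.89), though the sets were normalized separately.

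The counts of list members below come from the planned fit and were not made with each set's own spread. For p53-activated targets the difference was upward in 37 of 46 genes and downward in 2, or 39 and 2 adjusted over the list alone (adjusted p = 6.82e-25). For the pluripotency network it was downward in 33 of 44 and upward in 1, or 35 and 1 adjusted over the list alone (adjusted p = 2.62e-13). Both held with an estimated correlation, at adjusted p = 0.00229. FGF and ERK signalling had 14 of 23 downward and 2 upward, or 16 and 2 adjusted over the list alone, with Etv1 at -2.09 and Fgf15 at -2.06 (adjusted p = 2.63e-05, and adjusted p = 0.081 with an estimated correlation). The other probe of Etv1 gave -1.59. Cholesterol synthesis had 16 of 20 downward, or 17 adjusted over the list alone, with Ebp at -1.23 (adjusted p = 2.67e-06, and adjusted p = 0.254 with an estimated correlation). Wnt ligands had 4 of 19 upward, the same adjusted over the list alone, with Wnt8b at 1.94 and Wnt3 at 1.85 (adjusted p = 0.0204, and adjusted p = 0.717 with an estimated correlation). The Wnt call also ended with quantile normalization (adjusted p = 0.0818), with dim genes left out (adjusted p = 0.0547), and without R1E adriamycin replicate 2, untreated p53-/- replicate 3 or treated p53-/- replicate 2 (adjusted p = 0.0513, 0.156 and 0.0583). DNA methylation genes had 13 of 25 downward, or 16 and 1 upward adjusted over the list alone, with Tet2 at -1.30 (adjusted p = 0.00101, and adjusted p = 0.262 with an estimated correlation). Glycolysis and hypoxia response had 15 of 27 downward and 3 upward, or 16 and 3 adjusted over the list alone, with Ndrg1 at -1.63 (adjusted p = 0.00275, and adjusted p = 0.565 with an estimated correlation). Replication and G1/S genes had 14 of 41 downward, or 15 adjusted over the list alone, with Ccne1 at -1.17 (adjusted p = 0.00499, and adjusted p = 0.565 with an estimated correlation), and the call ended without untreated p53-/- replicate 3 (adjusted p = 0.074). Polycomb components had 13 of 28 downward and 1 upward, or 15 and 1 adjusted over the list alone, with Phf19 at -1.25 (adjusted p = 0.00656, and adjusted p = 0.306 with an estimated correlation). The LIF, STAT3 and BMP response had 12 of 23 downward and 5 upward, the same adjusted over the list alone, with Bcl3 at -1.72 (adjusted p = 0.00656, and adjusted p = 0.262 with an estimated correlation). For histone genes, with 6 of 24 upward and 2 downward, the list was not called (adjusted p = 0.303), nor were G2/M genes (adjusted p = 0.822).

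The planned fit, with 1 spread shared by both sets, gave 2571 genes with a higher and 3233 with a lower effect in R1E. In a second run of simulated arrays with the sets' own spreads that fit made too many false calls. These were 12.4% of calls with 4000 changed genes and 40.3% with 200, where the first run gave 38.4%. A fit with each set's own spread, added after the data were seen, gave 2065 and 2266 genes, with 5.5% and 12.6% false calls in the same simulations, and 4330 of its 4331 genes were among those of the planned fit. Differences of at least 2-fold numbered 671 upward and 350 downward in both fits, and every gene named above as differing passed both except Tigar, counted among the p53 targets (adjusted p = 0.118 with each set's own spread).

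Of the 779 genes that rose at least 2-fold in R1E, 772 had a larger effect there by the fit with each set's own spread, and their median log2 change in p53-/- cells was 0.15. Of the 292 that fell at least 2-fold, 282 did, with a median of 0.01 in p53-/- cells. Both groups were chosen on the same R1E arrays, which favours a larger effect there. In p53-/- cells 80.7% of the 779 also changed upward and 49.3% of the 292 downward, where the median over all genes was 0.058. Called changes shared by the lines numbered 1 higher and 15 lower, where independent lists would share 0.7 and 4.1, and the changes correlated across genes at r = 0.213.

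**Figure D3:**
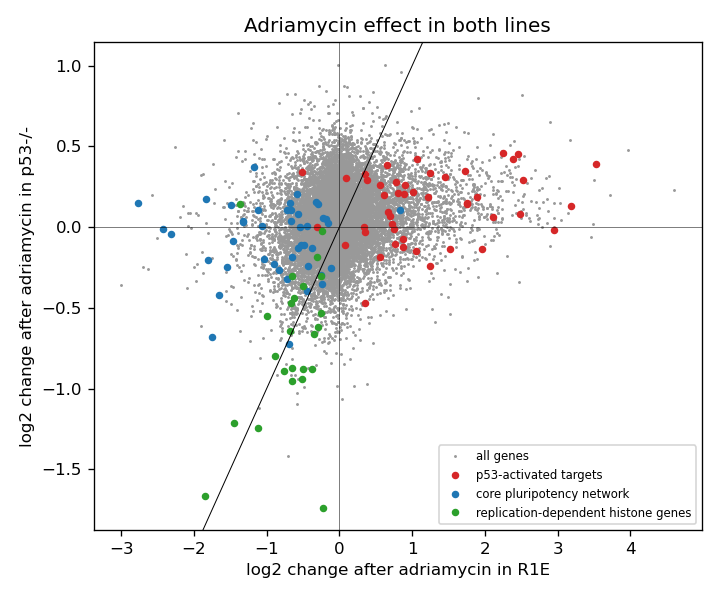
Log2 change after adriamycin in R1E (horizontal axis) against p53-/- cells (vertical axis), with 1 point per gene and a line of equal change. The p53-activated targets (median 0.891 in R1E, 0.169 in p53-/-) and pluripotency genes (-0.671 and -0.007) spread along the R1E axis, while histone genes (-0.638 and -0.653) lie low in both.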

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

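The tests of the mock arrays, of level among brighter genes, of the wider p53-/- spread, of the scale among large changes and of the share of stem cells, and the simulation without a difference, were chosen after the result was seen, and the 3 patterns weighed here were themselves chosen from the results.

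Differences between the lines drew attention through the test of the difference itself. The adriamycin effect was higher in R1E for 2571 genes and lower for 3233 by the planned fit. List medians of the difference were 0.84 for p53 targets, 0.14 for Wnt ligands, -0.67 for the pluripotency network, -0.50 for cholesterol synthesis, -0.39 for both the LIF, STAT3 and BMP response and FGF and ERK signalling, -0.37 for DNA methylation, -0.33 for glycolysis, -0.31 for polycomb components and -0.20 for replication genes. All 10 lists were also called with array weights per set, but only p53 targets and the pluripotency network with an estimated correlation. Gene differences were 4.37 for Them5, 3.52 for Cpz, 3.51 for Ppp1r36, 3.5 for Alox5, 3.47 for Gpx6, 3.21 for Scn3b, 3.14 for Tap1, 3.06 for Pm20d1, 3.05 for Fas, 1.70 for Mdm2 and 0.68 for Ccng1. Downward differences were -2.92 for Prdm14, -2.78 for Fgf17, -2.76 for Bmp4, -2.64 for Zic2, -2.46 for Zic5, -2.44 for Apela, -2.41 for Otx2, -2.37 for Emp1, -1.22 for Nanog, -1.07 for Zfp42, -0.54 for Sox2 and -0.40 for Esrrb. In 33 tests for an outlying array among 4 R1E arrays, 0 were found, where chance gives about 1 in 20. Probes with no single gene symbol, 7035 in number and outside the main comparisons, also changed: 1315 after adriamycin and 1102 after UV in R1E, 8 in p53-/- cells and 549 for the difference of effects.

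Other splits of the arrays bear on the counts. For each of the 3 R1E comparisons 1 of 35 splits, the real one, gave as many genes (9507, 8751 and 8370). The highest other split gave 0. A share of 1 in 35 is the smallest these splits allow, and it argues against chance differences between single arrays. The other splits place the treatment effect in the spread, which lowers their calls. Differences between cultures or batches are not excluded, since the labels do not say whether arrays came from separate cultures. For p53-/- cells 10 splits are too few for a share under 0.05; the real split gave 19 and the highest other 0. For the difference of effects, without the UV arrays, 1 of 100 regroupings, the real one, gave as many as 5228. Regroupings that mix the lines place a true difference between them in the spread, which lowers their calls. They also mix sets of unlike spread, so they cannot exclude chance. Set means were removed per gene beforehand, and in 20 simulations with no difference, each set's own spread and independent genes, the real grouping gave 0 to 11 calls. The highest other regrouping gave 1359, and its first group, which in the real grouping holds the 4 mock and 4 adriamycin R1E arrays, held 1 of each, so its other group was of R1E arrays alone.

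Long genes were lower after UV in R1E. Mock arrays or their normalization are argued against, since adriamycin against the same mock arrays gave a Spearman rho of 0.035. Genes not called for the difference of adriamycin effects gave -0.334, so the trend did not rest on the called genes. Those calls cannot be assigned to p53 and miss small differences, so short p53-dependent genes are not excluded as a part of the trend. Expression level was tested in 5 bins, which gave 0.007, -0.099, -0.253, -0.464 and -0.552 from the dimmest to the brightest. The prediction of a trend in every bin failed in the dimmest bins, at 0.007 and -0.099, and the trend grew stronger with level. But both bins above the median gave trends, the weaker -0.464, so level does not account for the brighter genes and stays open for the dim ones. Among 1569 genes above 100 kb that were not dim the trend with span continued (-0.142), as a length-dependent loss of transcripts after UV would give. That reading is a hypothesis: adriamycin in p53-/- cells also gave a trend, a rho of -0.141, and base composition, which can vary with span, was not tested.

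Few genes were called in p53-/- cells. For large changes both wider spread and a compressed scale are argued against: of 1071 genes changed at least 2-fold in R1E, the 95% interval in p53-/- cells held the R1E change for 0.56%, and for 1.21% after the p53-/- values were multiplied by 1.155, the ratio of the sets' SDs of gene levels. That rescaling left 5464 genes called for the difference in place of 5804, and 1 factor cannot move the 19 calls in p53-/- cells; a compression that differs between genes was not tested. Untreated replicate 3 stays open as a partial source: 442 genes were called without it, between the bounds set beforehand. Changes under 2-fold, and some of 2-fold, may have been missed. Of simulated 2-fold changes 69.4% were recovered with 200 changed genes and 95.9% with 4000. Moreover, p53 status cannot be told apart from line, set and processing tool.

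Most pluripotency genes fell in R1E and their effect differed in p53-/- cells. A lower share of stem cells would lower genes read only in them alike, and Pou5f1 had a log2 change of only -0.178, against a list median of -0.671. But 1 gene picked after the result cannot decide this, and whether the list members are specific to stem cells was not tested. With array medians aligned across the separately normalized sets, 21 of 44 members (47.7%) started at least 1 log2 unit lower in p53-/- cells. So did 126 of the 350 genes with at least a 2-fold lower effect in R1E (36%) and 8.8% of all genes. After rescaling by 1.155 these shares were 31.8%, 30.3% and 6.3%. Genes with at least a 2-fold higher effect in R1E also started that much lower more often than all genes, 129 of 671 (19.2%), or 16.8% after rescaling. Of all genes 35.9% were dim in untreated p53-/- cells, against 4.6% of the 350, so the share of all genes is not a like comparison. As far as these alignments hold, a lower start is argued against as the whole cause. The 14 network members that started less than 0.5 lower still had a median difference of -0.601, and the 23 such members after rescaling one of -0.472. The other members had medians of -0.722 and -1.07. But the untreated level is itself a term of the difference, so members with a lower start tend to a more negative difference by construction. The same holds for the 350 genes, which were chosen on that difference. Whether a lower start adds to the difference therefore stays open. Line and p53 status cannot be told apart here.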

How the results depend on the processing

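Quantile normalization of the lists, array weights in the list test and each set's own spread were chosen after the data were seen. Of 7392 values under an alternative, no called gene and no list's test changed direction, but 3 called lists had a median that turned sign: TGF-beta signalling (0.019) and the pluripotency network (0.024) in p53-/- cells without untreated replicate 2, the latter also without adriamycin replicate 3 (0.004), and homologous recombination between the agents with centring (-0.001); 6142 gene values kept their side of the threshold, 79 lost it and 10 gained it, and for lists 775 kept it and 103 lost it. Array median centring gave 9640 lower genes for adriamycin in R1E, and 1 higher gene in p53-/- cells. Requiring at least 1.5-fold left 1715 higher and 1214 lower for adriamycin in R1E, 1019 and 915 for UV, 965 and 407 for adriamycin against UV, 1549 and 1436 for the difference, and 8 genes lower in both lines; fewer genes can pass by construction. Lists called with an estimated correlation numbered 4, 3, 0, 0 and 2 (adriamycin in R1E, UV, adriamycin against UV, p53-/-, difference), and with fry 29, 27, 26, 1 and 23. Unadjusted, 7 and 3 lists passed with an estimated correlation where 0 did adjusted. Without dim genes 9 of 14 lists were called after UV, as Notch signalling, Wnt nuclear factors, homologous recombination, G2/M genes and the stress response lost their calls; the cause was not tested. In p53-/- cells a spread from all 18 arrays gave 1478 higher and 784 lower. But in simulated arrays 74.2% of such calls were false with 200 changed genes and 22.9% with 4000. Median changes of long genes turned sign in p53-/- cells without dim genes (-0.034), and for the difference at 50 kb (-0.01) and without dim genes (0.031), where the reported medians were 0.003 and 0; the cause was not tested.

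In R1E the deviations of same-numbered arrays correlated above 0.1 in 2 of 12 pairs, against 8 of 36 pairs with different numbers. Pairing by number was thus not seen in R1E, though differently numbered pairs ranged from -0.423 to 0.391. In p53-/- cells the correlation was above 0.1 in 1 of 3 same-numbered pairs (median 0.088) and 0 of 6 others (median 0.002). These p53-/- pairs are too few to tell whether the numbers pair the arrays. With the replicate block, calls were 4374 higher and 5050 lower for adriamycin in R1E, and 0 higher and 5 lower in p53-/- cells by limma, where 2425 genes passed unadjusted, the calls of Procr, Nrf1, Cdh11, Leng8, Muc1 and Ldoc1 ended (adjusted p from 0.0634 to 0.12), and so did the UV call of Wnt nuclear factors (adjusted p = 0.0548).

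Leaving out each array in turn gave 4113 to 4382 higher and 4761 to 4972 lower for adriamycin in R1E, 3964 to 4686 and 3861 to 4204 for UV, 3693 to 3917 and 3943 to 4289 for adriamycin against UV, and 2381 to 3046 and 2878 to 3674 for the difference. In p53-/- cells it gave 0 to 135 higher and 0 to 307 lower, the highest without untreated replicate 3; the lowest left 1457 genes unadjusted. Lists called ranged over 14 to 14, 13 to 15, 10 to 12, 10 to 14 and 9 to 11. Signal over background was not analysed here, and dim genes can have compressed changes.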

Other observations

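By limma camera, which compares a list with other genes, lists for other cell types were not called after adriamycin in R1E. Endoderm markers had a median log2 change of 0.004 (5 higher and 5 lower, adjusted p = 0.782), mesoderm markers -0.071 (3 higher and 4 lower, adjusted p = 0.823) and germ cell markers -0.031 (3 higher and 6 lower, adjusted p = 0.823). Adjusted over the list alone these counts were 6 and 5, 3 and 4, and 3 and 6. The mesoderm mean was 0.036, opposite in sign to its median. Ectoderm and neural markers had a median of -0.103 (4 higher and 8 lower, adjusted p = 0.166) and trophectoderm markers -0.104 (2 higher and 4 lower, adjusted p = 0.528), the same counts adjusted over the list alone. By limma fry, which tests only whether a list moves one way, both were called downward (adjusted p = 0.000818 and 0.0122). Genes of the 2-cell stage had the highest of these medians, 0.379, with 5 of 7 higher and 1 lower, or 5 and 2 adjusted over the list alone, but the list was not called by camera (adjusted p = 0.166), while fry called it upward (adjusted p = 4.61e-05). Nucleotide excision repair genes, which repair UV lesions, were not called by camera after UV, with 5 of 25 higher and 7 lower (adjusted p = 0.752), the same adjusted over the list alone. For ribosomal proteins the median was 0.017 after adriamycin in R1E (adjusted p = 0.837).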
